A study of Homo sapiens with 6 samples.

How the data were processed

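Total RNA of AGS cells, an established human gastric adenocarcinoma line, was sequenced in 6 libraries, 3 from cells without indomethacin and 3 from cells given 0.5 mM of it for 24 h. Libraries were made with a stranded total RNA kit after depletion of ribosomal RNA and read as pairs on a NovaSeq instrument, per the labels' protocols. Base calling with bcl2fastq, quality control with FastQC 0.11.7, trimming with cutadapt 1.16, alignment with HISAT2 2.1.0, SAMtools, counting with featureCounts and testing with DESeq2 are named, with genome build hg38, per the submitters' processing notes, which give neither the order nor the settings of these tools. Each deposited table holds the authors' raw counts for 1 library, with the exon coordinates, strand and length of each gene, per the file headers. The strand setting, the treatment of reads that map to several places and the annotation release were not given in the sources used here. How these were set bears on genes with near-identical copies, genes that overlap another gene and antisense genes, whose values are therefore uncertain. Exons of 52 of the 159 named genes overlapped exons of another gene with counts, 45 of them with a gene on the opposite strand.

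The counts were used as the authors deposited them. In every table the line of 1 gene was broken, so 3 of 60607 lines were left out and 60604 genes were read. Symbols came from a table of gene names and covered 60462 gene identifiers, and gene types came from GENCODE 29, which held 58336 of them. Total counts were between 17535435 and 23221077 per library, so that a gene with no count lay under 0.129 to 0.171 CPM, the level of 3 counts. Such floors and counting intervals cover counting error only. Every pair of libraries within a group differed by more than sampling noise (chi-square per degree of freedom 7.91 to 25.9), so all 6 were kept as separate samples. Groups were taken from the treatment each label names. The labels give no time for the control libraries, so whether their time in culture matched is not known.

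Genes were kept by edgeR's filterByExpr (edgeR 4.0.16, R 4.3.3), which left 17200, scaled by TMM and tested with edgeR's quasi-likelihood test (glmQLFit and glmQLFTest) with group as the only term. P-values were adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. Standard errors are those the test statistic implies. Gene levels are counts scaled by TMM to a common library size (CPM), given as mean ± SD (n = 3). Gene lists, 36 in number, were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, two-sided and adjusted over the 34 lists with 5 or more genes tested. Camera with an estimated correlation and fry were run beside it. Members were counted over all genes and adjusted over the list alone. Shares of counts were compared with a two-sided exact permutation test, which cannot go below p = 0.1 with 3 against 3.

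Named genes followed a rule. It took SIRT3, PTGS1 and PTGS2, then the 10 highest and 10 lowest log2 fold changes among genes past the threshold with a mean of 5 CPM or more, no overlap between groups and a symbol that is not a clone name or pseudogene. It also took up to 4 members of each list with the smallest adjusted p, and the 3 genes with most counts. The groups, the tests, the gene lists, this rule and the alternatives were fixed before the data were examined. A gene named in the text outside the rule, such as the few members that moved against their list, was chosen after its values were seen.

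The alternatives were limma-voom and DESeq2 1.42.0 in place of edgeR, RLE and upper-quartile factors in place of TMM, library sizes without mitochondrial and small structured RNAs, no filter on low counts, a filter of 1 CPM in 3 libraries, an offset for gene length, the replicate number as a block, and each replicate left out in turn. A fold threshold of log2 1 was also applied, and shares were recomputed over nuclear-encoded genes. The 3 count tests and camera were tested on simulated data drawn from mean levels of the 3 control libraries and library sizes of all 6. In these data 200 genes were changed, far fewer than in the real ones, and edgeR tested 16033 genes. There edgeR recovered 40.3% of the genes changed 1.5-fold, 86.6% of those changed 2-fold and 97.0% of those changed 4-fold, each with the right sign, and 10 of its 159 calls were false. False calls were 10 of 157 with limma-voom and 18 of 170 with DESeq2, which recovered 37.3% and 47.8% of the genes changed 1.5-fold. With no list changed camera called 0 of 34 lists, and with the proteasome list lowered it called that list and 0 others. Simulated genes were drawn independently of each other, so this cannot show how the preset correlation serves lists whose genes vary together. In the real data the estimated correlation reached 0.87, for the mitochondrially encoded mRNAs. The simulation was first run after the first fit of the real counts, and no setting was changed because of it. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.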

Results

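Gene expression was measured by total RNA sequencing in AGS cells, a human gastric adenocarcinoma line, after 24 h with 0.5 mM indomethacin, a non-steroidal anti-inflammatory drug (NSAID) that inhibits cyclooxygenases. The series was set up to ask how such drugs act on gastric cells, with the mitochondrial deacetylase sirtuin 3 as the proposed shared target. There were 3 control and 3 indomethacin libraries, with total counts of 20983189, 23221077 and 21919853 in the control libraries and 20094302, 19323461 and 17535435 in the indomethacin libraries. Nothing in the labels says that the 3 samples of a group came from separate cultures, so p-values measure the spread between these samples, which may be technical. Coordinates are those of the deposited tables, on build hg38.

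Most of the genes tested differed between the indomethacin and the control libraries. The carcinoembryonic antigen gene CEACAM5, a cell surface glycoprotein, rose from 2.72 ± 0.338 to 890 ± 22.6 CPM (log2 fold change 8.35, SE 0.15), and the gene of the tight junction protein claudin 2, CLDN2, fell from 330 ± 60.5 to 4.40 ± 0.521 CPM (-6.22, SE 0.18; both mean ± SD, n = 3). The receptor phosphatase gene PTPRH rose from 1.93 ± 0.271 to 298 ± 122 CPM, the filamin gene FLNC from 0.333 ± 0.0800 to 49.5 ± 7.76 CPM and the uridine phosphorylase gene UPP1 from 4.13 ± 0.635 to 474 ± 144 CPM. Among the largest falls were ANKRD1, a target of the YAP pathway (143 ± 34.3 to 2.94 ± 0.783 CPM), the amino acid transporter gene SLC7A8 (33.7 ± 9.41 to 0.699 ± 0.147), the lectin gene REG1A (27.1 ± 8.38 to 0.556 ± 0.327), FAM111B (56.8 ± 8.56 to 1.37 ± 0.466) and the kinase gene MAP2K6 (21.1 ± 2.36 to 0.489 ± 0.193). RNASE1 and SERTAD4 fell with log2 fold changes of -5.50 and -5.81. Of 17200 genes tested, 10591 passed edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p under 0.05, with 5264 higher and 5327 lower, and 5675 of them changed at least 2-fold. With upper-quartile factors the split was 6124 higher and 4686 lower. The groups did not overlap in 67.0% of the genes tested, against 10% by chance. CEACAM5 lies on chromosome 19 from 41708585 to 41730433 and CLDN2 on chromosome X from 106900164.

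Several of the largest changes were set against very few counts in one group. TDRD9, a helicase gene of the germ line, had 2 counts over the control libraries and 607 over the indomethacin libraries, a ratio of 342 (95% counting interval 94.3 to 2830). KLHDC7B had 3 and 668 counts (ratio 251, 85.5 to 1220), and SPRR2D, a gene of the cornified envelope of squamous cells, had 5 and 638 (ratio 144, 61.3 to 445). In the other direction, IGFBP5, which binds insulin-like growth factors, had 733 counts in control and 3 in indomethacin, a ratio of 217 (73.9 to 1050), and the sodium-proton exchanger gene SLC9A4 had 704 and 4, a ratio of 156 (60.7 to 575). The antisense gene PDE7B-AS1 had 2 and 599 counts (ratio 338, 93.1 to 2790), and 452 of its exonic bases overlap PDE7B on the other strand, so its value is uncertain. HSPA6 (log2 fold change 7.80) and AKR1C1 (6.71) also rose but share sequence with close copies.

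SIRT3, the gene of the sirtuin in the title (chromosome 11, 215030 to 236931, minus strand, identifier ENSG00000142082), fell 1.52-fold, from 12.9 ± 2.25 to 8.51 ± 0.905 CPM (log2 fold change -0.60, SE 0.17; edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0063; n = 3), and was lower in 3 of 3 indomethacin libraries than in any control. Its exons overlap those of RIC8A over 84 of 5553 bases. Of the 7 sirtuins, NAD-dependent deacylases, 4 rose. The nucleolar SIRT7 went from 16.3 ± 0.973 to 37.3 ± 3.98 CPM (1.19), SIRT1 from 30.0 ± 0.563 to 56.8 ± 1.78 CPM (0.92), and SIRT6 and SIRT2 had log2 fold changes of 0.91 and 0.75. SIRT3 was the 1 sirtuin that fell. The list as a whole did not pass camera (median 0.75, adjusted p = 0.078, and adjusted p = 0.33 with an estimated correlation), but passed with DESeq2 (adjusted p = 0.037), with no filter (0.042) and with fry (0.0013).

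PTGS2, the gene of the inducible cyclooxygenase (chromosome 1, 186671791 to 186680922), rose from 3.66 ± 0.714 to 33.2 ± 10.6 CPM (log2 fold change 3.18, SE 0.22; edgeR adjusted p = 4.0e-08; n = 3). PTGS1, the constitutive cyclooxygenase, had 1 count over all 6 libraries and was under the floor of 3 counts in both groups. Of 13 genes tested for prostaglandin synthesis and receptors, 9 fell, among them the prostaglandin transporter SLCO2A1 (log2 fold change -3.94), the phospholipase PLA2G4A that frees arachidonic acid (26.3 ± 1.68 to 6.77 ± 0.752 CPM) and the prostaglandin-degrading enzyme HPGD (24.6 ± 5.02 to 4.56 ± 2.74). PTGS2 and AKR1C3 (0.94), a reductase of prostaglandins and steroids, rose. The list was lower by camera (median -0.65, adjusted p = 0.045, and adjusted p = 0.33 with an estimated correlation). That call was lost with DESeq2 (adjusted p = 0.068), with a filter of 1 CPM (0.091) and with an offset for gene length (0.059), within a range of 0.00046 to 0.33 over the alternatives.

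**Figure D1:**
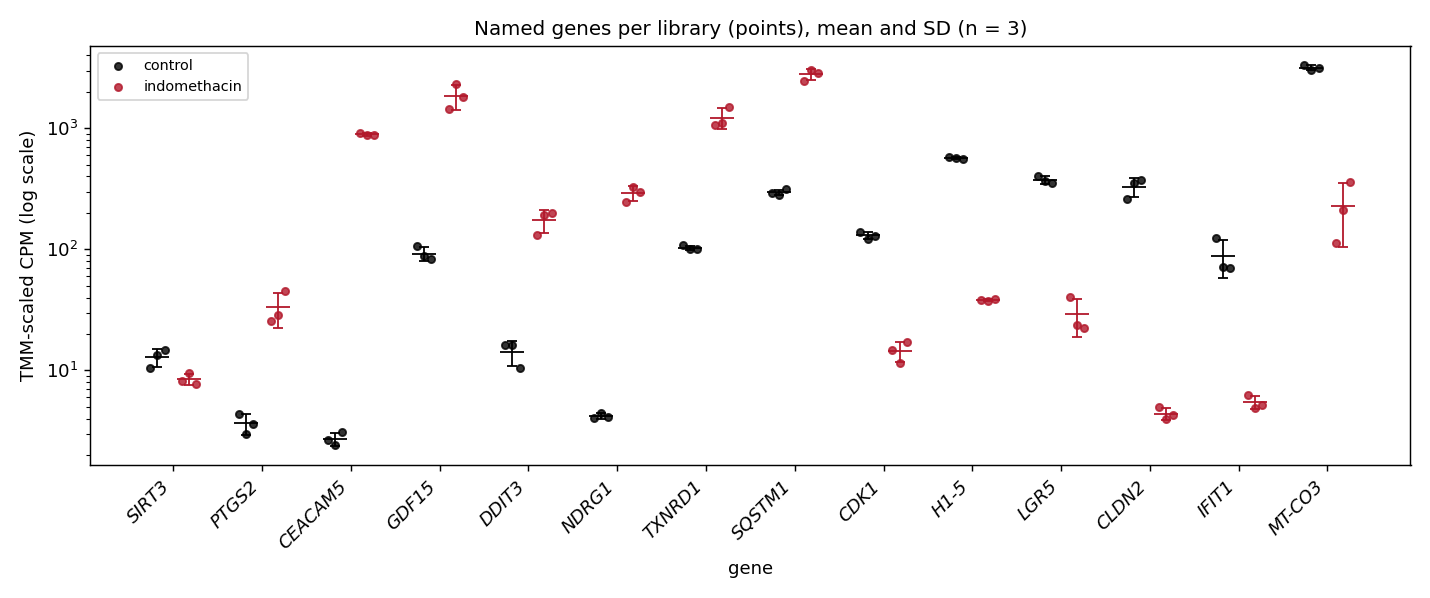
TMM-scaled CPM on a log axis for 14 genes in each control (black) and indomethacin (red) library, with the mean and SD of 3 libraries. The 2 groups do not overlap for any gene shown, from SIRT3 (12.9 against 8.51 CPM) to CEACAM5 (2.72 against 890 CPM).

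Genes of cell division fell together. All 31 tested genes of G2 and mitosis fell (median -2.63, camera adjusted p = 5.3e-18, and adjusted p = 0.33 with an estimated correlation), including the mitotic kinase CDK1 (130 ± 8.93 to 14.4 ± 2.80 CPM), the kinesin KIF23 (118 ± 11.2 to 14.2 ± 1.19) and the centromere proteins CENPF (534 ± 17.8 to 74.3 ± 10.6) and CENPE (-2.63). Of 37 genes of S phase and DNA replication, 36 fell and 1 rose (median -2.16, camera adjusted p = 8.4e-17, and adjusted p = 0.33 with an estimated correlation). UHRF1, which maintains DNA methylation, went from 49.7 ± 4.34 to 2.08 ± 0.614 CPM, the helicase subunits MCM3 and MCM4 had log2 fold changes of -2.79 and -3.22, and GINS1 of -3.27, while the licensing factor CDC6 rose by 0.73. Of 40 replication-dependent histone genes, whose mRNAs carry no poly(A) tail, 38 fell (median -2.39, camera adjusted p = 1.3e-20, and adjusted p = 0.33 with an estimated correlation). H1-5 on chromosome 6 (27866792) fell from 570 ± 11.9 to 38.3 ± 0.815 CPM, and H2AC12, H2BC9 and H2BC7 had log2 fold changes of -3.40, -3.04 and -3.35. Histone genes are near-identical copies of each other, so single values are uncertain.

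The lists of Wnt targets, ribosome biogenesis and the proteasome were also lower by camera with a preset correlation, and that of cytosolic ribosomal proteins was slightly higher. Of 17 Wnt and beta-catenin targets, 14 fell (median -1.53, camera adjusted p = 0.00016, and adjusted p = 0.33 with an estimated correlation). The stem cell receptor LGR5 (chromosome 12, from 71439798) fell 12.8-fold (log2 fold change -3.68, SE 0.20), TNFRSF19 from 120 ± 8.88 to 12.5 ± 1.25 CPM and cyclin D1, CCND1, from 242 ± 23.3 to 51.2 ± 15.8, and the secreted Wnt antagonist DKK1 had a log2 fold change of -2.77. The transcription factor MYC (1.03), also in the immediate-early list, and the hyaluronan receptor CD44 (0.38) rose. Of 30 genes of ribosome biogenesis, 18 fell and RRP12 (0.77) rose (median -0.49, camera adjusted p = 0.00057, and adjusted p = 0.33 with an estimated correlation). NHP2, NOP56, NOLC1 and DKC1, which act with small nucleolar RNAs, had log2 fold changes of -1.44, -1.33, -1.19 and -1.02. NHP2 shares 414 of 1434 exonic bases with RMND5B on the other strand. Of 31 proteasome subunits 18 fell, led by PSMA4 (163 ± 8.35 to 69.5 ± 6.80 CPM), PSMB2 (-0.96), PSMB3 (-1.10) and PSMD2 (-0.81); the median was -0.44 (camera adjusted p = 0.00096, and adjusted p = 0.57 with an estimated correlation). Of 74 cytosolic ribosomal proteins, 21 rose and 4 fell over all genes, and 18 rose and 3 fell adjusted over the list alone (median 0.17, camera adjusted p = 0.026, and adjusted p = 0.74 with an estimated correlation). RPL28, RPS9 and RPL12 had log2 fold changes of 0.76, 0.78 and 0.63, and RPL6 (-0.67), RPL22 (-0.33), RPS7 (-0.30) and RPL5 (-0.27) fell. Ribosomal proteins have many processed pseudogenes, and this call was lost without control replicate 1 (adjusted p = 0.092), control replicate 2 (0.26, median 0.08) or indomethacin replicate 3 (0.19, median 0.08), and with DESeq2, no filter (median 0.06) or fry, within a range of 0.00069 to 0.74 over the alternatives.

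Genes of mitochondrial respiration were lower from both genomes. Of 66 nuclear-encoded subunits of the respiratory chain, 62 fell, or 63 adjusted over the list alone (median -0.87, camera adjusted p = 1.1e-14, and adjusted p = 0.33 with an estimated correlation). The ATP synthase subunits ATP5F1A (359 ± 17.4 to 125 ± 6.31 CPM), ATP5MF (-1.81), ATP5MC1 (-2.49) and ATP5PB (-1.37) led them, and NDUFA13 (0.91) of complex I rose. Of 24 genes of the TCA cycle, which shares 4 succinate dehydrogenase subunits with the list above, 18 fell (median -0.81, camera adjusted p = 0.00016, and adjusted p = 0.33 with an estimated correlation). IDH2 went from 41.0 ± 4.03 to 9.11 ± 1.83 CPM, SDHC, FH and PDHB had log2 fold changes of -1.23, -1.18 and -1.23, and the pyruvate carrier MPC1 rose (0.52). Of the 13 mRNAs of the mitochondrial genome, 12 fell over all genes and 13 adjusted over the list alone (median -1.98, camera adjusted p = 8.6e-06, and adjusted p = 0.36 with an estimated correlation). MT-CO3 (chromosome M, 9207 to 9990) fell from 3170 ± 163 to 227 ± 123 CPM, MT-ND3 (10059 to 10404) from 60.7 ± 2.99 to 2.39 ± 1.41, MT-CO2 from 689 ± 28.2 to 141 ± 60.3 and MT-ND1 from 170 ± 7.22 to 42.2 ± 16.4. Mitochondrial genes have copies in the nuclear genome, so their values are uncertain.

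Along the mitochondrial genome the falls were uneven. MT-ND3, with a log2 fold change of -4.71 ± 0.25 (SE), lies beside MT-ND4L (-0.49, edgeR adjusted p = 0.051) and MT-ND4 (-0.57, edgeR adjusted p = 0.0046). The 12S rRNA MT-RNR1 had a log2 fold change of 0.23 (edgeR adjusted p = 0.22) and the 16S rRNA MT-RNR2 of -0.47 (edgeR adjusted p = 0.055), and neither passed. MT-RNR2 did pass with limma-voom (adjusted p = 0.0060), DESeq2 (3.6e-05), no filter (5.0e-08), an offset for gene length (0.033) and the replicate number as a block (0.012), and without control replicate 2 (edgeR adjusted p = 0.017), control replicate 3 (0.038), indomethacin replicate 1 (0.027) or indomethacin replicate 3 (0.017). Of 22 mitochondrial tRNAs, 6 had enough counts to be tested and all 6 fell, from -1.90 to -4.79. The tRNAs, MT-ND4 and MT-ND4L were singled out after their values were seen. Mitochondrially encoded genes took 24.3% ± 2.15 of all counts in control and 18.4% ± 1.54 in indomethacin libraries, and their mRNAs 0.733% ± 0.0160 and 0.132% ± 0.0470 (exact permutation test, two-sided, p = 0.1, the smallest possible; n = 3).

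**Figure D2:**
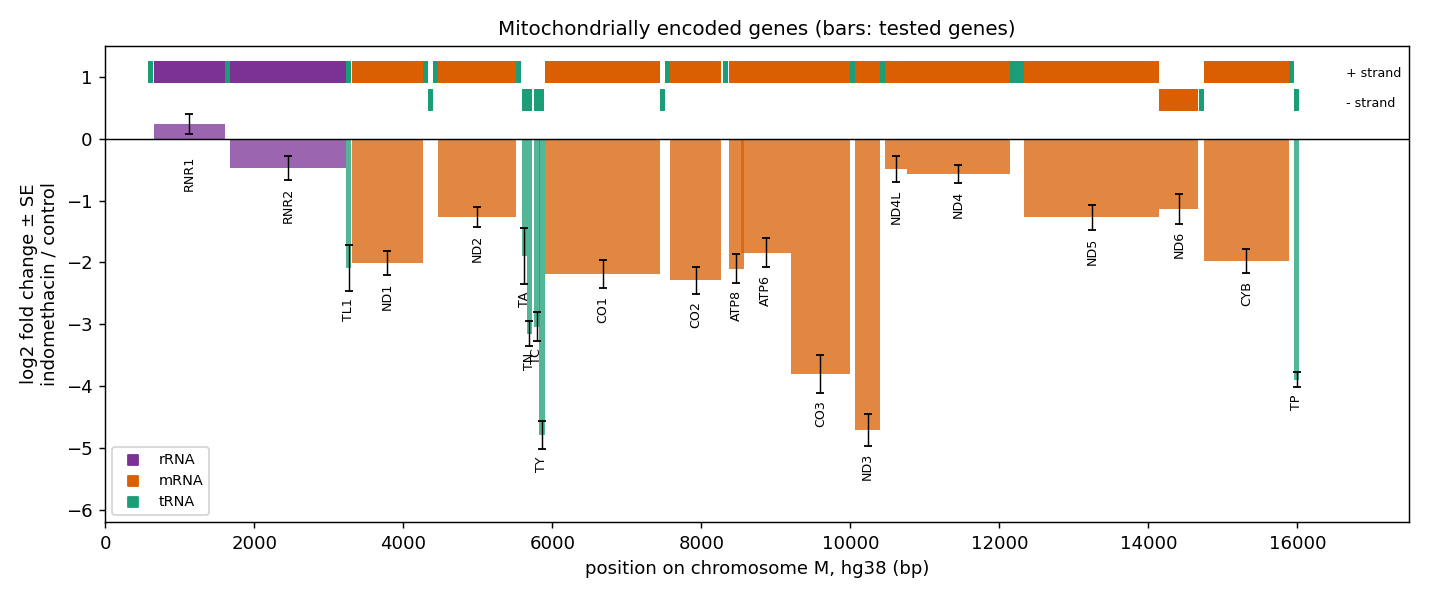
Log2 fold change with its SE (bars) of the mitochondrially encoded genes tested, against position on chromosome M (bp, hg38), with all annotated genes drawn above by strand and type. MT-ND3 (-4.71) and MT-CO3 (-3.80) stand beside MT-ND4 (-0.57), and MT-RNR1 lies at 0.23.

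Other lists of mitochondrial and energy metabolism held members in both directions and did not pass camera. Of 28 genes of mitochondrial biogenesis and turnover, 6 rose and 11 fell (median -0.12, adjusted p = 0.45, median -0.31 without control replicate 1 and 0.00 with upper-quartile factors), with TFAM, which packages mitochondrial DNA, at 91.3 ± 5.10 and 29.6 ± 4.09 CPM and the mitophagy receptor CALCOCO2 at 51.4 ± 5.15 and 137 ± 9.24. Of 18 mitochondrial chaperones and proteases 8 fell, such as the prohibitin PHB1 (-1.17) and TRAP1 (-0.83), and LONP1 (1.05), HSPA9 (0.95), HSPD1 (0.69), DNAJA3 (0.39) and YME1L1 (0.31) rose (median -0.20, or -0.08 with upper-quartile factors, adjusted p = 0.44). TRAP1 shares 1477 of 5183 exonic bases with DNASE1 on the other strand. Of 21 glycolysis genes 6 rose and 12 fell (median -0.59, adjusted p = 0.13, but 0.0018 with DESeq2 and 0.0041 with no filter, and up to 0.59 with an estimated correlation), with the lactate exporter SLC16A3 at 2.01 and PGAM1 and GPI at -1.85 and -1.81. Of 23 genes of fatty acid oxidation and PPAR targets 12 fell, HADH (-1.48) and SLC25A20 (-1.68) among them, and 5 rose, or 6 adjusted over the list alone (median -0.49, or -0.32 with a filter of 1 CPM, adjusted p = 0.22, but 0.030 with no filter, and up to 0.58 with an estimated correlation). The 5 were CREB3L3, a transcription factor of fasting (1.14 ± 0.404 to 76.4 ± 4.21 CPM), the lipid droplet protein PLIN2 (5.46), ANGPTL4 (1.63), ACADVL (1.21) and CPT1A (0.54). By fry, which does not compare a list with other genes, the lists of glycolysis, fatty acid oxidation, mitochondrial biogenesis and mitochondrial chaperones passed (adjusted p = 0.011, 0.0098, 0.020 and 0.045). Of 24 cholesterol synthesis genes 17 fell (median -1.17, camera adjusted p = 1.2e-05, and adjusted p = 0.33 with an estimated correlation). The synthesis enzymes DHCR7 and FDPS had log2 fold changes of -2.35 and -1.87.

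The lists of the integrated stress response and of ER chaperones were higher by camera with a preset correlation, and those of tRNA synthetases and heat shock proteins did not pass. Of 29 genes of the integrated stress response, 23 rose and 2 fell over all genes, and 23 rose and 3 fell adjusted over the list alone (median 1.46, camera adjusted p = 9.3e-08, and adjusted p = 0.33 with an estimated correlation). The stress cytokine GDF15, also a p53 target, went from 92.3 ± 12.8 to 1858 ± 429 CPM, DDIT3 (CHOP) from 14.3 ± 3.36 to 173 ± 37.5, the phosphatase subunit PPP1R15A from 83.5 ± 16.7 to 573 ± 131 and the amino acid transporter subunit SLC3A2 from 248 ± 18.3 to 1127 ± 111. DDIT3 shares 355 of 1307 exonic bases with MARS1 on the other strand, so its value is uncertain. SESN2 is shared with the p53 list, SLC7A11 with the NRF2 list and SLC7A5 with the aryl hydrocarbon receptor list. PSPH (-0.80) and GPT2 (-0.59), enzymes of serine and alanine synthesis, fell. Of 24 genes of ER chaperones and ER-associated degradation 12 rose (median 0.46, camera adjusted p = 0.0059, and adjusted p = 0.58 with an estimated correlation), led by DNAJB9 (10.2 ± 0.662 to 123 ± 29.3 CPM), SEL1L (1.96), EDEM1 (1.67) and SYVN1 (2.35). Without indomethacin replicate 3 the median of this list was 0.22. The folding factors PDIA3 (-0.62), PDIA6 (-0.76) and CALR (-0.65) fell. Of 20 cytosolic tRNA synthetases, 11 rose and 6 fell (median 0.41, camera adjusted p = 0.062), with WARS1 at 2.35 and SARS1 at 1.28. Without control replicate 2 or indomethacin replicate 1 the synthetases passed (camera adjusted p = 0.042 and 0.045). They also passed with DESeq2 (adjusted p = 0.0028), no filter (0.038), an offset for gene length (0.040) and fry (0.0053). The range over the alternatives was 0.0028 to 0.56. Of 16 heat shock proteins and cytosolic chaperones, 7 rose, BAG3 (1.21) and HSPH1 (0.85) among them, and HSPB1 (-1.01) and HSPA4 (-0.49) fell (median 0.19, camera adjusted p = 0.15). HSPA1A and HSPA1B, at 1.87 and 2.18, are near-identical copies. The median was 0.01 without indomethacin replicate 3 and also smaller without control replicate 2. Without indomethacin replicate 1 the list passed (camera adjusted p = 0.035, within a range of 0.035 to 0.74 over the alternatives).

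Lists of oxidative stress, hypoxia and p53 targets were higher by camera with a preset correlation, and those of apoptosis and autophagy did not pass. Of 31 antioxidant genes and NRF2 targets 21 rose and 7 fell (median 0.94, camera adjusted p = 0.00096, and adjusted p = 0.33 with an estimated correlation). The thioredoxin reductase TXNRD1 went from 104 ± 3.94 to 1227 ± 245 CPM and GCLC, of glutathione synthesis, from 44.7 ± 1.03 to 517 ± 118. The ferritin gene FTH1 (3.94) has many pseudogenes and shares 1267 of 2004 exonic bases with BEST1 on the other strand. NQO1 is also in the aryl hydrocarbon receptor list. Of 15 hypoxia genes, of which BNIP3 is also in the mitochondrial turnover list, 8 rose and P4HA1 (-0.82) fell (median 0.83, camera adjusted p = 0.0052, and adjusted p = 0.33 with an estimated correlation). NDRG1 went from 4.22 ± 0.220 to 291 ± 42.0 CPM, the angiogenic factor VEGFA from 162 ± 21.9 to 747 ± 92.9, and BHLHE40 and ERO1A had log2 fold changes of 0.92 and 1.04. Of 26 p53 targets 14 rose (median 0.43, camera adjusted p = 0.0096, and adjusted p = 0.33 with an estimated correlation). The cell cycle inhibitor CDKN1A went from 175 ± 9.07 to 489 ± 42.3 CPM, the death receptor TNFRSF10B from 97.3 ± 7.09 to 427 ± 58.9 and PLK3 from 6.77 ± 0.329 to 30.0 ± 4.48, while DDB2 (-1.25), TP53I3 (-0.99), SESN1 (-0.69) and BAX (-0.28) fell. Of 29 apoptosis regulators 11 rose and 9 fell (camera adjusted p = 0.73). The median was -0.02, but the mean was 0.03 and the test leaned higher, and the median ran from -0.12 to 0.10 over the alternatives. TNFRSF10B, BAX, BBC3, PMAIP1 and FAS are in this list too, and BIRC3 is shared with the NF-kappaB list; the survivin gene BIRC5, shared with the mitosis list, stood at -3.51 and BCL2L2 at 1.54. Of 27 autophagy and lysosome genes 10 rose, or 11 adjusted over the list alone, and 6 fell (median 0.24, camera adjusted p = 0.087, within a range of 0.00018 to 0.37 over the alternatives, passing with DESeq2 and fry). Without control replicate 1 the median was 0.15. The autophagy receptor SQSTM1 went from 297 ± 15.2 to 2786 ± 284 CPM and MAP1LC3B from 21.3 ± 0.538 to 212 ± 23.1.

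Signalling and immune lists went both ways. Of 24 immediate-early and AP-1 genes 19 rose and SPRY2 (-1.23), which restrains growth factor signalling, fell (median 1.28, camera adjusted p = 5.7e-06, and adjusted p = 0.33 with an estimated correlation). KLF4 went from 9.38 ± 2.32 to 76.3 ± 5.09 CPM, PHLDA1 from 39.9 ± 6.09 to 269 ± 57.6 and IER5 from 36.8 ± 0.913 to 86.9 ± 5.72, and FOSL1 had a log2 fold change of 2.13. Of 21 interferon-stimulated genes 18 fell (median -2.55, camera adjusted p = 2.1e-06, and adjusted p = 0.33 with an estimated correlation). The antiviral IFIT1 went from 89.0 ± 30.6 to 5.45 ± 0.681 CPM, IFI6 from 44.4 ± 1.44 to 5.22 ± 0.955, OAS3 from 39.2 ± 3.56 to 6.65 ± 1.02 and IFI27 from 16.3 ± 2.61 to 1.46 ± 0.283, while the transcription factor IRF7 rose (1.83). Of 21 NF-kappaB and inflammatory genes 10 rose, such as RELB (2.27) and NFKB2 (1.80), and CXCL10 (-3.72), CXCL1 (-1.66), CSF1 (-1.64) and NFKB1 (-0.50) fell (median 0.33, camera adjusted p = 0.062). Without control replicate 1 this list passed (median 0.50, camera adjusted p = 0.038), as it did with DESeq2 (median 0.82), with no filter (median 0.78) and with fry (within a range of 0.00046 to 0.33 over the alternatives). Of 6 aryl hydrocarbon receptor targets TIPARP (1.57), CYP1A1 (2.47), SLC7A5 (1.29) and NQO1 (0.35) rose and ALDH3A1 (-1.06) fell (median 0.82, camera adjusted p = 0.38). UGT1A6 (-2.48) shares exons with its neighbours in the UGT1A cluster. Of 4 metallothioneins tested, too few for camera, MT1X rose (0.50) and MT1F fell (-1.16). MT1X no longer passed without control replicate 2 (edgeR adjusted p = 0.11) or indomethacin replicate 2 (0.055), or with DESeq2 or no filter.

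Genes of gastric epithelium were lower as a list by camera with a preset correlation, and the junction and mesenchymal lists did not pass. Of 19 gastric and intestinal epithelial genes 13 fell (median -1.38, or -0.87 with DESeq2, camera adjusted p = 0.0081, and adjusted p = 0.33 with an estimated correlation). The microvillus protein villin, VIL1, went from 207 ± 24.3 to 25.2 ± 7.86 CPM, pepsinogen C, PGC, from 20.8 ± 1.17 to 4.48 ± 0.0430, and the transcription factor GATA4 from 71.6 ± 4.49 to 28.2 ± 0.272. VIL1 shares 3045 of 6891 exonic bases with USP37 on the other strand. The trefoil factors TFF1 (0.774 ± 0.644 to 25.2 ± 8.46 CPM) and TFF2 (5.22), ANXA10 (3.13) and the mucin MUC17 (4.92) rose. Of 22 epithelial junction and keratin genes 8 rose (median 0.23, camera adjusted p = 0.12, median 0.08 without control replicate 1), with occludin, OCLN, at 72.6 ± 2.22 and 288 ± 34.5 CPM and CLDN1 at 1.54, while PKP2 (-2.17), EPCAM (-0.68), KRT8 (-0.55) and ESRP2 (-0.42) fell. Of 10 mesenchymal genes 4 rose, SNAI1 (3.24), ZEB1 (2.78) and COL1A1 (1.02) among them, and VIM (-3.28), TAGLN (-2.45), PDGFRB (-4.52) and TGFBI (-1.92) fell (camera adjusted p = 0.95). The median was 0.18 while the mean was -0.25 and the test leaned higher, and without indomethacin replicate 1 the median was -0.05. TAGLN shares 2233 of 6550 exonic bases with PCSK7 on the other strand. Of 20 markers of blood and endothelial cells only the lysozyme gene LYZ, which gastric epithelium also expresses, had enough counts to be tested, and it fell from 1099 ± 435 to 121 ± 3.83 CPM.

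Of 12 small structured and nuclear RNAs tested, 7 rose, or 6 adjusted over the list alone, and 0 fell (median 0.49, camera adjusted p = 0.022, and adjusted p = 0.37 with an estimated correlation). The nuclear RNAs NEAT1 (219 ± 94.4 to 2323 ± 284 CPM) and MALAT1 (1354 ± 358 to 7466 ± 1401) lie on chromosome 11. KCNQ1OT1 (1.23), an antisense gene, shares 121 exonic bases with KCNQ1 and is uncertain. The call was lost without indomethacin replicate 3 (median 0.26, camera adjusted p = 0.055) and with an offset for gene length (median 0.06, adjusted p = 0.17), within a range of 0.0014 to 0.37 over the alternatives. RN7SL1, an RNA of the signal recognition particle with near-identical copies, took 4.54% ± 0.475 of counts in control and 7.41% ± 0.813 in indomethacin libraries, and MT-RNR2 took 21.9% ± 2.23 and 16.2% ± 1.36 (exact permutation p = 0.1 each, n = 3). MT-RNR1 took 1.70% ± 0.111 and 2.04% ± 0.215 (exact permutation p = 0.2, n = 3). The share of ribosomal protein genes was 4.07% ± 0.137 and 4.71% ± 0.372 (exact permutation p = 0.1, n = 3), or 5.38% ± 0.225 and 5.77% ± 0.385 of nuclear-encoded counts (exact permutation p = 0.3, n = 3), and that of the 50 genes with most counts 39.2% ± 1.15 and 40.4% ± 1.85 (exact permutation p = 0.5, n = 3). The small structured and nuclear RNA list took 29.5% ± 1.57 and 28.2% ± 1.40 (exact permutation p = 0.5, n = 3), most of it the mitochondrial rRNAs (23.6% and 18.2%). Its 18 nuclear members took 7.79% ± 0.551 and 12.25% ± 1.004 of nuclear-encoded counts (exact permutation p = 0.1, n = 3). Across the 34 lists tested, camera called 21, 8 higher and 13 lower. With an estimated correlation it called 0, with a smallest adjusted p of 0.33 and 1 list under 0.05 before adjustment, and fry called 29. In 29 of the 36 lists the counts adjusted over the list alone were the same as over all genes, and the other 7 are given with their lists.

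**Figure D3:**
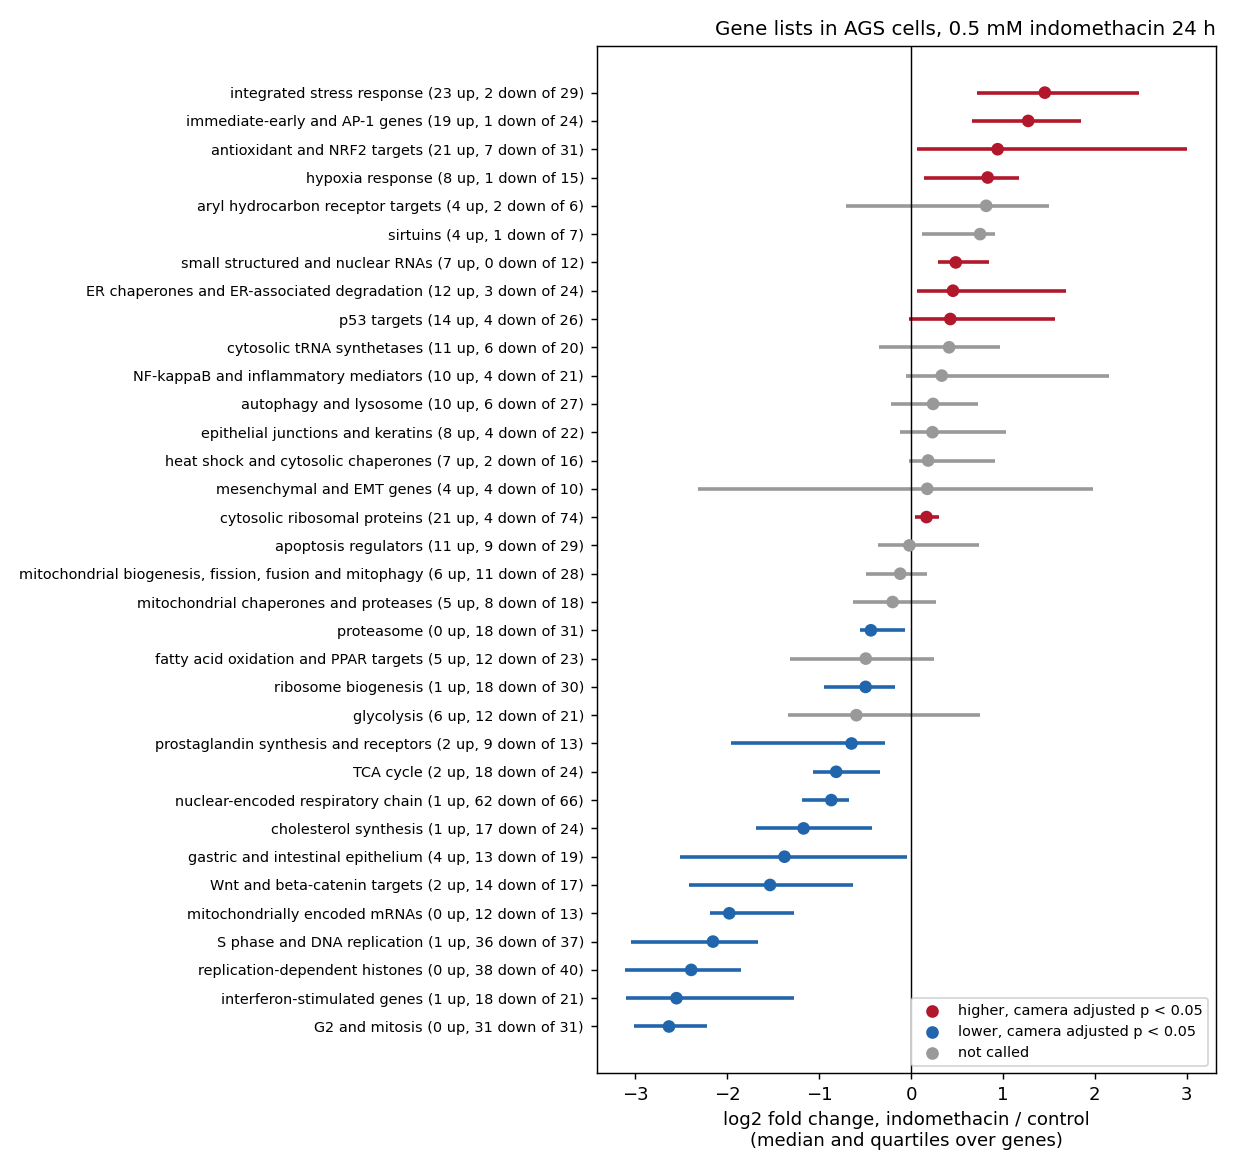
Median (point) and quartiles (line) of the log2 fold change over the tested genes of each of 34 lists, coloured by the camera call with a preset correlation. Medians run from -2.63 for G2 and mitosis to 1.46 for the integrated stress response, and none of the 21 calls held with an estimated correlation.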

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

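The tests and alternatives in this part were chosen before the data were examined. Of 10591 genes changed, 5675 passed with a change of at least 2-fold, 2999 higher and 2676 lower. The other count settings gave 9625 to 11722 changed genes, with 10601 when the replicate number was a block, and every gene called both there and in the result as reported kept its direction. Upper-quartile factors moved the median of all genes by 0.12 and no filter by -0.11. SIRT3 stayed between -0.79 and -0.48 (highest edgeR, limma or DESeq2 adjusted p 0.031), PTGS2 between 2.89 and 3.31 and CEACAM5 between 8.23 and 8.47. With an estimated inter-gene correlation 0 of 34 lists passed camera, 1 had an unadjusted p under 0.05, and fry called 29. The median of the apoptosis regulators was -0.08 (-0.0847) with DESeq2 and -0.12 (-0.1246) with no filter, and that of the mesenchymal genes 0.2962 with upper-quartile factors and between -0.0475 and 0.2711 without each replicate, within -0.05 to 0.60 over all alternatives; the cause was not tested. Over nuclear-encoded genes alone, the share of small structured and nuclear RNAs differed by 4.464 points (18 genes, against -1.242 for 20 genes over all counts) and that of the genes with most counts by 7.157 (46 genes, against 1.194 for 50), so mitochondrial genes leave both the class and the total. That of protein-coding genes differed by -6.372 (-0.221 over all counts). Across named genes, 2361 values kept direction and side of the threshold, 9 gained a call and 5 lost one. Across lists these were 516, 24 and 32, with 4 medians or test directions reversed. RN7SL1 no longer passed with an offset for gene length (log2 fold change 0.32). Counting noise limits genes near the floor of 3 counts.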

Other observations

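The families in this paragraph were explored only after the data were seen: 119 families sharing a symbol root were tested, camera called 15, and 0 passed with an estimated correlation (smallest adjusted p 0.73). Of 48 MRPL genes, proteins of the large mitochondrial ribosomal subunit, 38 fell and 1 rose (median -0.73, camera adjusted p = 3.5e-06), and of 28 MRPS genes of the small subunit 18 fell and 1 rose (median -0.48, camera adjusted p = 0.019). Of 16 tetraspanins 13 fell and 0 rose (median -1.11, camera adjusted p = 0.0011). Of 20 golgin genes 16 rose and 0 fell (median 1.06, camera adjusted p = 0.0011), with GOLGA2 at 39.8 ± 5.04 and 102 ± 23.5 CPM (mean ± SD, n = 3), though the GOLGA6 and GOLGA8 genes are near-identical copies. Of 21 nucleoporins 15 fell and 2 rose (median -0.64, camera adjusted p = 0.019). Of 15 IFT genes of ciliary transport 10 fell and 0 rose (median -0.64, camera adjusted p = 0.034), with IFT25 at 45.9 ± 5.73 and 20.7 ± 1.93 CPM. No family named here changed direction under another scaling.

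Of the tests below, those of the 10 splits, of low abundance and of the ER chaperone call without each indomethacin library were written before their results were seen, and the other 6 after. Of the 10 splits of the 6 libraries into 3 and 3, only the real one gave 10591 changed genes and 21 lists. Every other split gave 0 changed genes but 11 to 16 lists, so camera with the preset correlation called lists where no gene passed. Those splits still held unequal numbers of control libraries on their 2 sides, so their calls do not measure a false call rate. With 10 splits no share under 0.05 can be reached.

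Of the 13 mitochondrially encoded mRNAs 12 fell (median -1.98, and adjusted p = 0.36 with an estimated correlation). All 6 tested mitochondrial tRNAs fell too (median -3.09). The rest of the 22 annotated had too few counts to be tested. Of the 6, 5 lie on the minus strand, and the strand setting of the counts is not known. Whether their reads are independent of the mRNAs was not tested, so they do not decide whether mRNA alone changed. Less mitochondrial RNA of every kind stays open, since MT-RNR1 lay 2.21 above the mRNA median and MT-RNR2 stood at -0.47, but rRNA was depleted from these libraries and its counts may reflect that step. The mRNAs and 404 annotated nuclear copies of mitochondrial genes, rRNA copies included, together reached at most 0.266 of the control level in any indomethacin library. This argues against reads having been assigned to those copies instead. Reads that map to several places may have been counted in neither, so a loss of such reads is not excluded. No scaling brought the median closer to 0 than -1.86, and an effect of indomethacin on mitochondrial RNA stays open as a hypothesis.

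Of 1929 long non-coding RNAs tested, of the lincRNA and antisense types, 788 rose and 229 fell (median 0.59). Antisense genes made up 1148 of those tested and 455 of those that rose, and their values are uncertain without the strand setting. Of the 781 lincRNAs, 333 rose and 130 fell (median 0.59). The median of all 1929 lay 0.30 above the highest of 1000 draws of protein-coding genes matched on abundance. This argues against low abundance alone. Over the 9 pairs of libraries the median gain per kb was at least 60.05 times that of olfactory receptor genes for the higher ones. Those were chosen for having risen, so their ratio is no test. For all 1929 the ratio was 10.99 to 22.54. These RNAs passed a filter on counts, which keeps genes high in indomethacin alone, and the olfactory receptor genes were not filtered. A larger gain could come from that difference, so the ratio does not decide on genomic DNA. Olfactory receptor genes rose too, from 0.00988 to 0.0117 CPM per kb in control to 0.0206 to 0.0222 in indomethacin libraries. Some added DNA or background is therefore not excluded. An earlier form without olfactory pseudogenes has the same limit, and the value over all 1929 was added last. More nuclear or unspliced RNA may explain part of the rise and stays open. The median of sense-intronic RNAs was 0.73, and MALAT1, NEAT1 and the uncertain KCNQ1OT1 rose. These named RNAs are long non-coding themselves, so their rise is not separate support. A stricter form of the test on sense-intronic RNAs, tried first, was not met, since 0.73 is under the interquartile half-range of 0.737.

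The ER chaperone list varied between indomethacin libraries: its camera adjusted p was 7.3e-05, 0.0068 and 0.0321 without replicates 1, 2 and 3, so the call held without each, though not with an estimated correlation (adjusted p = 0.58), and its median was 0.22 without replicate 3 against 0.46 with all. The mean log2 change was larger in replicate 3 than in replicate 1 by 0.71 for this list (95% interval over resampled genes 0.54 to 0.88) and differed by -1.13, -0.46 and -0.47 in size for mitochondrially encoded mRNAs, S phase and G2. Each difference was at least 1.64 times the range of the 3 control libraries, and the ER chaperones differed in the opposite direction to the other 3 lists. This compares 1 library with 1 other. The genes of a list vary together (estimated correlation 0.73 for ER chaperones), so resampling them does not cover spread between libraries. By the rule written for this test, these values counted against a single exposure factor for each library. That rule rests on the resampled genes, so such a factor stays open here. The test was tried in 4 forms after the values were seen. Under the ratio of the replicates with resampled genes the question also stayed open (2.79 for ER chaperones, -9.71 to 18.6). Other sources of the spread were not tested, and 3 control libraries give a rough range.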
